A study of Mus musculus with 12 samples.

How the data were processed

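Single-nucleus RNA was measured in cortex from 8-week-old C57BL/6 mice. Per the labels, mice received a severe traumatic brain injury by controlled cortical impact, in which a piston strikes the exposed cortex, and tissue was taken at 6 h, 2 d or 4 d. Control mice form the fourth group. Each of the 4 groups holds 3 libraries, which the labels call biological replicates, 12 in all.

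Per the labels' protocols, nuclei from frozen tissue were purified on a sucrose gradient and processed with 10x Genomics 3' chemistry. The deposited matrices hold raw UMI counts (distinct tagged transcripts) per gene and barcode, made by the authors with Cell Ranger, version 6.0.2 per the file headers and 6.0.3 per the submitters' processing notes, against mm10. The annotation release and the inclusion of intronic reads are not given in the sources used here. All matrices list the same 32285 genes. A deposited list names the nuclei that the submitters kept, with the UMI count per nucleus, and holds no cell type. Every listed barcode was found in its own library's matrix. The listed UMI count of a nucleus was at most 43 below the sum of its deposited counts. A total of 4 columns of that list were not used here.

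The matrices hold 162907 barcodes, between 9533 and 24143 per library, of which 144921 were listed as kept. Of the 17986 barcodes not kept, 85.74% lay above the highest UMI count among the kept nuclei of their library. UMI totals over kept nuclei ran from 20161604 to 40815733 per library. No doublet caller was run. The upper limit on UMIs in the submitters' list may have removed doublets, and nuclei above the 95th percentile of UMIs of their class and library were left out as an alternative. Intervals and floors below cover counting error only. The edgeR, DESeq2 and permutation p-values measure the spread between libraries. Camera p-values at the preset correlation rest on the spread between genes, with list members taken as nearly independent. They are not by themselves evidence from replicates.

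All barcodes were normalised to 10000 UMIs, log-transformed and clustered without batch correction, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15). Of 30 clusters, 25 were named from marker lists. A marker counted as detected in a cluster when at least 10% of nuclei held a UMI and the share was at least 1.5 times that of the median cluster, and 3 detected markers were required. A cluster stayed unnamed if more of its 10 leading genes were on another marker list or the proliferation list than on its own. For this, 1 gene against 0 was enough. It also stayed unnamed if its UMIs were over 1.5 times those of the other clusters of its name with 3 or more markers of another class detected. This naming rule and the resolution were settled after the clusters were seen. The 7 classes analysed hold 75.34% of kept nuclei, or 109183, in 20 clusters. The 5 unnamed clusters hold 16.79%: 37.01% ± 31.43 of control nuclei (SD, n = 3), 8.02% ± 5.2 at 6 h, 16.24% ± 17.54 at 2 d and 7.78% ± 1.96 at 4 d. The remaining nuclei resembled striatal or hippocampal neurons, ependymal cells or choroid plexus, and were not tested.

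Shares of nuclei were tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood test with all kept nuclei as library size and Benjamini-Hochberg adjustment over 7 classes and 3 times, and with an exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3. For expression, raw counts were summed per library and class where a library held at least 20 nuclei of the class, and tested with edgeR's robust quasi-likelihood test (TMM factors, filterByExpr) in 1 fit of all 12 libraries per class. Adjusted p-values are Benjamini-Hochberg over the genes of a class and contrast, at a threshold of 0.05. An F-test in the same fit asked which genes differed among the 3 injury times. CPM were computed by edgeR from the summed counts with TMM factors.

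The 23 gene lists were tested in 7 classes at 3 times with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, with adjustment over all 483 tests. The lists cover immediate early genes, heat shock, the integrated stress and unfolded protein response, DNA damage and p53 targets, axon injury and regeneration, hypoxia and glycolysis, synapse and neurotransmission, reactive astrocytes, astrocyte homeostasis, homeostatic and disease-associated microglia, inflammatory cytokines and NF-kB, the interferon response, complement and antigen presentation, proliferation, iron handling with ferroptosis and NRF2, inflammasome with pyroptosis and necroptosis, myelin, reactive oligodendrocytes, blood-brain barrier, endothelial activation, extracellular matrix, and lipid and cholesterol. The groups, tests, thresholds, markers, lists and the rule for named genes were fixed before the data were examined. By that rule the text names, per class and time, up to 2 genes with the largest rise and 2 with the largest fall among called genes with an average log2 CPM of at least 5 and no overlap between injured and control libraries. It adds up to 3 called members per described list, and members followed over several times. Predicted gene models, mitochondrial, ribosomal protein, haemoglobin and Y-linked genes, and Xist and Tsix, were left out. The lists described, and the members followed over times, were chosen after their values were seen. An earlier, longer choice of followed members was shortened after the alternatives had been computed, and the dropped ones include uncalled genes whose direction changed between alternatives.

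Where control libraries held no UMI of a gene, the fold is given against a floor of 3 counts over the control group, and with 1 to 3 control UMIs the ratio of pooled counts is given with an exact binomial 95% interval. Coordinates are from GENCODE M21 on GRCm38 (mm10), 1-based. All 57 named genes matched it by identifier, as did 32158 of the 32285 genes.

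Libraries were compared over 10690 genes with an average log2 CPM of at least 3. Hierarchical clustering of these correlations, run after the data were seen, gave a set A of 5 libraries and a set B of 7, named below. The labels give no batch. Counts of libraries within a group differed by 18.46 to 309.45 times the value expected from counting error alone (chi-square per degree of freedom), so none was deposited in duplicate. The replicate numbers are not stated to pair mice across groups.

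The edgeR steps were tested on simulated data with 200 changed genes, after the fits to the real libraries had first been run. For 6 h against control, genes changed 4-fold were recovered in 62.1% of cases in excitatory neurons, 80.3% in astrocytes and 74.2% in microglia, and genes changed 2-fold in 8.96%, 11.9% and 11.9%. Changes of 2-fold and below are therefore mostly not detectable here.

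Alternatives covered DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, only the compared groups in the fit, nuclei whose own markers match their class, equal numbers of nuclei, the replicate number as a block, leaving out each library, other tests and denominators for shares, and fry or an estimated correlation for lists. Added after the data were seen were all deposited barcodes, finer clusters, the library set as a term, leaving out the 2 libraries with most unnamed nuclei, cluster 3 counted as excitatory neurons, and the contrast of 4 d with 2 d.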

Results

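Nuclei from mouse cortex were profiled in uninjured controls and at 6 h, 2 d and 4 d after controlled cortical impact, with 3 libraries per group. The submitters kept 144921 nuclei, between 8157 and 21322 per library. The median kept nucleus held between 1263.5 UMIs in control 3 and 3159 in the first 4 d library. Among the kept nuclei, 53987 were excitatory-neuron-like, 11674 inhibitory-neuron-like, 11480 astrocyte-like, 11567 oligodendrocyte-like, 5386 like oligodendrocyte precursors, 7979 like microglia and macrophages, and 7110 vascular. These classes are called by their plain names from here on.

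The 12 libraries fell into 2 sets that cross the groups. Controls 1 and 2 and all 6 h libraries formed set A, and control 3 with all 2 d and 4 d libraries formed set B. Correlations of log expression across genes ran from 0.877 to 0.986 within the sets and from 0.807 to 0.923 between them, where genes are not independent replicates. The sets were the same in all 7 classes. 4 d library 3 was closer to controls 1 and 2 than the other libraries of set B were. It correlated at 0.923 and 0.921 with controls 1 and 2 and at 0.922 with control 3, against 0.956 to 0.97 with the other 2 d and 4 d libraries. Within a class, different clusters held most nuclei of each set. For astrocytes, cluster 18 held 89.1% of the nuclei of controls 1 and 2 and 97% at 6 h, while cluster 6 held 99.3% in control 3, 99.8% at 2 d and 99.5% at 4 d. Oligodendrocytes were likewise divided between clusters 16 and 9, microglia between clusters 24 and 10, and inhibitory neurons between clusters 19 and 13, with cluster 15 shared. Excitatory neurons of set A lay mostly in clusters 2 and 7, those of control 3 in cluster 4 (92.9%), and those at 2 d and 4 d in clusters 1, 5 and 21. Precursors (cluster 12) and vascular cells (clusters 17, 23 and 27) shared their clusters across sets. A comparison of 2 d or 4 d with control therefore sets 3 libraries of set B against 2 of set A and 1 of set B. A fit with the set as a term rests on control 3 against controls 1 and 2. With that term, 2 d and 4 d are in effect compared with control 3 alone, and 6 h with controls 1 and 2 alone. Calls at 2 d or 4 d with the term thus rest on 1 control library. At 6 h the term and leaving out control 3 are not separate checks.

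Astrocytes and microglia took larger shares of the nuclei after injury, and inhibitory neurons a smaller one. Astrocytes, which support neurons and react to damage, rose from 5.21% ± 1.03 of kept nuclei in controls (SD, n = 3) to 9.82% ± 1.8 at 2 d and 10.14% ± 1.87 at 4 d. Microglia and macrophages, the immune cells of the tissue, rose from 3.53% ± 1.22 to 7.89% ± 2.01 at 4 d. Inhibitory neurons fell from 9.77% ± 1.35 to 6.7% ± 0.65 at 2 d. The log2 fold changes were 0.91 and 0.96 for astrocytes (edgeR adjusted p = 0.0145 at both times), 1.16 for microglia (edgeR adjusted p = 0.0313) and -0.54 for inhibitory neurons (edgeR adjusted p = 0.0249). In each of these 4 comparisons all 3 injured libraries lay beyond all 3 controls, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow.

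Vascular cells made up 3.43% ± 0.46 of control nuclei and 7.39% ± 0.37 at 4 d, with an edgeR adjusted p of 0.0689, and microglia 6.69% ± 1.85 at 2 d, also with an edgeR adjusted p of 0.0689. Excitatory neurons made up 25.2% ± 24.3 of control nuclei, 53.57% ± 5.84 at 6 h, 34.45% ± 17.13 at 2 d and 34.51% ± 6.01 at 4 d, and no difference passed the test. Control 2 held 126 of them. Unnamed cluster 3 held 31.3% ± 31.8 of control nuclei and 1.35% ± 1.41 at 6 h. It had 7 detected excitatory markers, but 0 of its 10 leading genes were on the excitatory list and 1 on the vascular list. With cluster 3 counted as excitatory neurons, controls 1, 2 and 3 held 5267, 6954 and 10614 of them, against 2364, 126 and 10612 without it. The control share above thus depends on this naming, and shares with cluster 3 included were not tested. No share of oligodendrocytes or precursors passed the test at any time. In simulations a 2-fold change of share at 6 h was recovered in 1 of 20 draws for excitatory and 14 for inhibitory neurons. For oligodendrocytes it was 3 and for precursors 8, so changes may be missed. All 4 calls ended with the library set as a term (edgeR adjusted p between 0.167 and 0.231). With that term the log2 fold changes were 0.97 for astrocytes at 2 d and 1.02 at 4 d. They were 1.33 for microglia and -0.40 for inhibitory neurons. The 3 glial calls ended among non-neuronal nuclei alone (0.37, 0.20 and 0.42, edgeR adjusted p between 0.252 and 0.489), and shares of 1 whole are not independent. Leaving out control 2 ended all 4, with edgeR adjusted p of 0.101 for inhibitory neurons, 0.0599 for astrocytes at both times and 0.114 for microglia. The inhibitory call also ended without 2 d library 1 (0.0534) or 2 (0.0630), the astrocyte call at 2 d without 2 d library 2 (0.0628), and the microglial call without control 3 (0.119), 2 d library 2 (0.0628) or 4 d library 3 (0.113). Microglia passed at 2 d without control 1 (0.0269) or 2 d library 1 (0.0439), and vascular cells passed at 2 d and 4 d without 6 h library 1 (0.0251 and 0.0168).

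**Figure D1:**
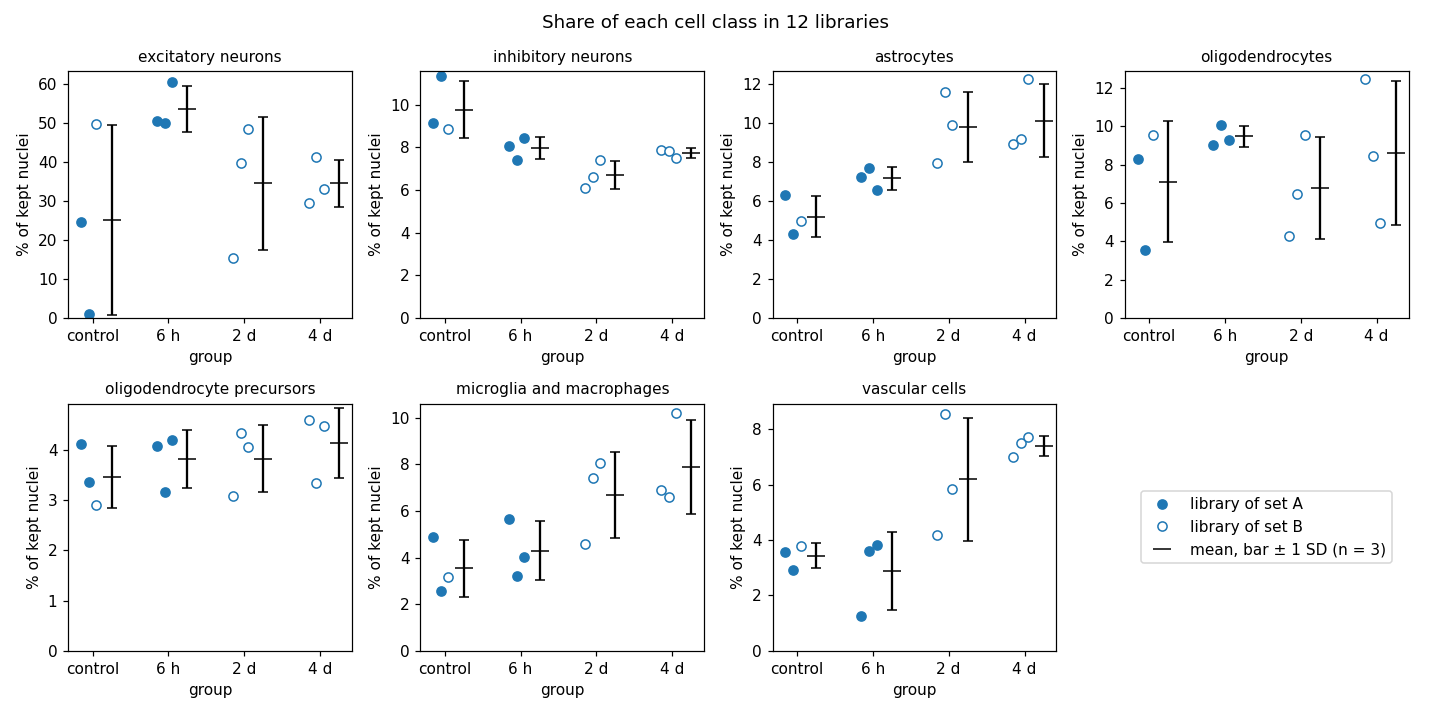
Share of each of the 7 classes among the kept nuclei of a library, in percent, for controls and at 6 h, 2 d and 4 d. Points are libraries, filled for set A and open for set B, and dashes with bars the mean of 3 libraries with the SD; astrocytes go from 5.21% in controls to 10.14% at 4 d.

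At 6 h, the comparison of injured with control cortex asks for the earliest response. Genes called in microglia and macrophages included several chemokines. Ccl3 and Ccl4, chemokines that attract immune cells, rose by log2 fold changes of 8.00 ± 0.90 (SE) and 6.42 ± 0.79, with edgeR adjusted p of 0.000997 and 0.00264. Ccl4 went from 2.82 CPM ± 2.46 in controls to 273 CPM ± 162 (SD, n = 3). Ccl3 had 1 UMI in all controls and 339 at 6 h, a ratio of 342 (95% counting interval 61.0 to 13500). Cxcl2, which attracts neutrophils, had no UMI in control microglia and 281 at 6 h, at least 94.5-fold higher (edgeR adjusted p = 0.0328). Slc7a11, the cystine transporter used for glutathione synthesis, rose by 3.98 ± 0.58 (edgeR adjusted p = 0.00504), Hmox1, the haem-degrading enzyme, by 4.99 ± 0.99, and Slc39a14, a zinc and iron importer, by 2.36 ± 0.42. Il7r, the interleukin 7 receptor, fell by 2.57 ± 0.43 on the log2 scale, the sulfotransferase gene Gal3st4 by 2.21 ± 0.45 and Crybb1, a crystallin gene used as a microglial marker, by 1.82 ± 0.35.

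In microglia at 6 h, 12 of 14 measured members of the inflammatory cytokine and NF-kB list rose when adjusted over the list alone and 5 over all genes tested, with a median log2 fold change of 2.54. Its camera adjusted p was 1.82e-18, and the adjusted p = 0.33 with an estimated correlation. In the iron handling, ferroptosis and NRF2 list 7 of 16 rose adjusted over the list alone and 3 over all genes tested (camera adjusted p = 8.46e-06, adjusted p = 0.33 with an estimated correlation). The homeostatic microglia list moved down with a median of -0.78: 5 of 15 members fell adjusted over the list alone and 1 over all genes tested (camera adjusted p = 7.62e-06, adjusted p = 0.449 with an estimated correlation). P2ry12, the purinergic receptor of resting microglia, went from 421 CPM ± 84.3 to 245 CPM ± 76.3, with an edgeR adjusted p of 0.219. Immediate early genes, which respond within minutes to stimulation, had a median of 1.19 (camera adjusted p = 1.11e-05, adjusted p = 0.449 with an estimated correlation), with 9 of 19 members up adjusted over the list alone and 0 over all genes tested by edgeR.

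In vascular cells at 6 h, Adamts9, a secreted metalloprotease, rose by 4.26 ± 0.55 from 18.4 CPM ± 13.1 to 331 CPM ± 181 (edgeR adjusted p = 0.00407), and Lcn2, which binds bacterial iron carriers, by 6.22 ± 1.08 (edgeR adjusted p = 0.0301). The adhesion molecule Icam1 rose by 2.28 ± 0.49 and the neutrophil chemokine Cxcl1 by 3.93 ± 0.80. The transporter gene Slc22a6 fell by 2.64 ± 0.54 and the RAN-binding protein gene Ranbp3l by 2.38 ± 0.50. Ranbp3l was a leading gene of cluster 23. That cluster held 29% of vascular nuclei at 6 h, 38.8% in controls 1 and 2 and 35.9% in control 3. Whether cell mix adds to its fall was not tested. In the endothelial activation and sprouting list 5 of 13 members rose adjusted over the list alone and 2 over all genes tested (camera adjusted p = 4.19e-08, adjusted p = 0.33 with an estimated correlation), and in the cytokine list 7 of 8 and 2 (camera adjusted p = 9.65e-08, adjusted p = 0.33 with an estimated correlation). The reactive astrocyte list also rose here (camera adjusted p = 1.8e-07, adjusted p = 0.33 with an estimated correlation). Its 4 members past the test over all genes were Lcn2, Stat3, Socs3 and Osmr, and 7 of 17 rose adjusted over the list alone. Stat3 encodes a transcription factor of cytokine signalling, Socs3 (log2 fold change 2.65 ± 0.53) its feedback inhibitor and Osmr (2.44 ± 0.46) the oncostatin M receptor, none specific to astrocytes; Stat3 was named after its values were seen.

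Astrocytes at 6 h raised Sbno2, a transcriptional regulator induced by interleukin signalling, by 4.10 ± 0.54 from 20 CPM ± 3.79 to 348 CPM ± 226 (edgeR adjusted p = 0.0075), Socs3 by 4.59 ± 0.77 and Cdkn1a, the p53 target that arrests the cell cycle, by 3.20 ± 0.52. Myoc, the gene of myocilin, fell by 2.34 ± 0.41 and the fatty acid binding protein gene Fabp7 by 1.80 ± 0.35. The reactive astrocyte list rose, with 11 of 17 members up adjusted over the list alone, 1 over all genes tested and a median of 2.16 (camera adjusted p = 2.1e-09, adjusted p = 0.399 with an estimated correlation). Immediate early genes rose with a median of 1.26, with 11 of 20 members up adjusted over the list alone and 0 over all genes tested by edgeR (camera adjusted p = 3.09e-08, adjusted p = 0.449 with an estimated correlation). Neuronal RNA in astrocytes was also higher at 6 h. Of 1765 genes at least 1.5 times higher in control excitatory neurons than in control astrocytes, 448 were lower and the median was 0.29. Camk2a was at 484 CPM ± 66.3 against 371 CPM ± 112 and Nrgn, a calmodulin-binding gene of neurons, at 1590 CPM ± 385 against 1190 CPM ± 336. In the DNA damage and p53 list 3 of 11 members rose adjusted over the list alone and 1 over all genes tested (camera adjusted p = 0.0102, adjusted p = 0.33 with an estimated correlation). Gfap, the astrocyte filament gene, was at 120 CPM ± 33.4 in controls and 363 CPM ± 244 at 6 h (edgeR adjusted p = 0.175). 6 h library 2 stood apart. Gfap was at 83.8 CPM there, below each control, against 477 and 530 CPM in libraries 1 and 3. Serpina3n was at 12.4 CPM against 111 and 95.8 CPM.

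In oligodendrocytes at 6 h, Cdkn1a rose by 3.12 ± 0.42 and Sbno2 by 2.23 ± 0.30 (edgeR adjusted p = 0.0178 for each). The reactive oligodendrocyte list, immediate early genes and DNA damage and p53 targets had medians of 0.59, 0.92 and 0.18. Their camera adjusted p was 8.58e-05, 7.18e-06 and 0.00759, and 0.412, 0.449 and 0.33 with an estimated correlation. Adjusted over the list alone, 1, 8 and 3 members of these lists rose, and 1 member of the last fell. In precursors, immediate early genes and the reactive oligodendrocyte list moved up with medians of 1.20 and 0.95. Adjusted over the list alone, 8 and 2 members rose. Camera adjusted p was 1.28e-06 and 9.41e-06, and 0.446 and 0.337 with an estimated correlation. By the measure used for astrocytes, neuronal genes were slightly higher too, with medians of 0.09 in precursors, 0.05 in oligodendrocytes and 0.11 in microglia. In precursors 682 of 1613 were lower. In precursors edgeR called 0 single genes, with 1590 genes at an unadjusted p under 0.05 and 145 called by DESeq2.

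In inhibitory neurons at 6 h, Prkab2, a subunit of the energy sensor AMPK, rose by 1.90 ± 0.27 from 42.0 CPM ± 10.6 to 156 CPM ± 58.4 and the signalling gene Ccdc88c by 1.54 ± 0.23 (edgeR adjusted p = 0.0236 for each). Ccl4 had no UMI in control inhibitory neurons and 61 at 6 h, at least 30.8-fold higher (edgeR adjusted p = 0.0236), at 9.49 CPM ± 4.00 against 273 CPM in microglia. The cytokine list moved up in inhibitory and excitatory neurons (camera adjusted p = 0.000835 and 8.7e-05, adjusted p = 0.33 for both with an estimated correlation). Immediate early genes moved up there with medians of 1.13 and 0.66. Their camera adjusted p was 0.000118 and 0.0491, and 0.519 and 0.733 with an estimated correlation. RNA of excitatory neurons was also higher in inhibitory neurons. Slc17a7 was at 367 CPM ± 40.5 against 304 CPM ± 0.927 and Camk2a at 576 CPM ± 72.2 against 322 CPM ± 43.8.

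At 6 h, edgeR called 145 genes in microglia (115 up, 30 down), 69 in vascular cells (62 up, 7 down), 34 in astrocytes (29 up, 5 down), 12 in inhibitory neurons (10 up, 2 down), 4 in oligodendrocytes (3 up, 1 down) and 1 in excitatory neurons (up). With cluster 3 counted in, excitatory neurons had 229, so their count depends on that naming. With DESeq2's size factors the split was 5 up and 1 down in excitatory neurons and 3 up and 0 down in oligodendrocytes. Over the classes, 265 genes were called, 372 with the library set as a term, and 119 in both. The split was 220 up and 45 down without the term and 208 up and 164 down with it. Among the 27 named calls at 6 h, 14 were called and all 27 kept their sign with the set as a term. With that term Ccl3 had a log2 fold change of 10.34 and Cxcl1 of 3.31. The total moved to 6370 without control 1, 56 without control 2, 378 without control 3, 31 without 6 h library 1, 1446 without 6 h library 2 and 17 without 6 h library 3. It was 155 without 2 d library 2, 165 without 4 d library 1 and 172 without 4 d library 2. Adamts9, Ccl3, Ccl4 in microglia and Slc7a11 were called in every fit that left out 1 library. The highest adjusted p of the others was between 0.0818 and 0.281. Of the 27 calls, 20 ended without control 2, 13 without control 3, 20 without 6 h library 1 and 22 without 6 h library 3. Between 2 and 8 ended without each of the other libraries. The list calls of DNA damage and p53 targets ended without control 1 (0.0784 in astrocytes, 0.0922 in oligodendrocytes). That of immediate early genes in excitatory neurons ended without control 2 (0.187), control 3 (0.155), 6 h library 1 (0.467), 6 h library 3 (0.654) or 4 d library 3 (0.0514).

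**Figure D2:**
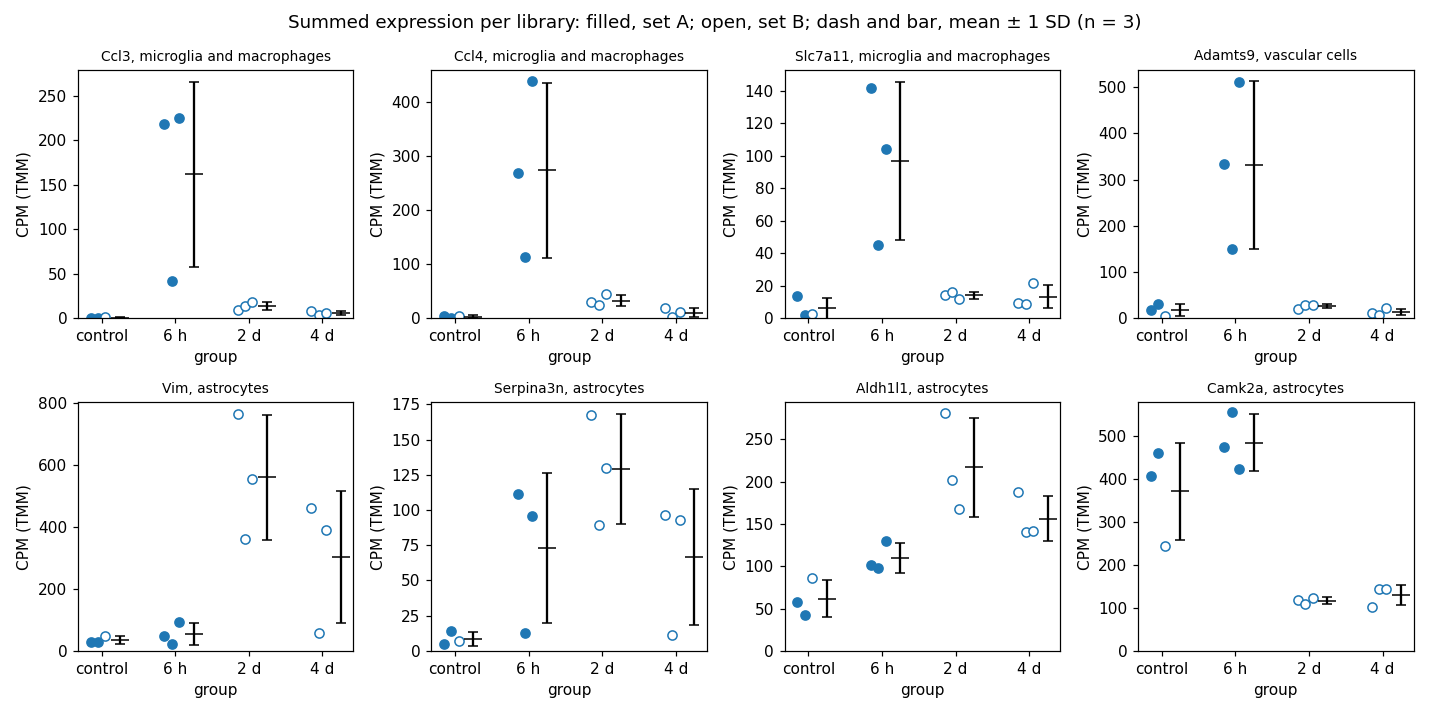
CPM of 8 named genes per library, for controls and at 6 h, 2 d and 4 d. Points are libraries, filled for set A and open for set B, beside the mean with the SD; Ccl4 in microglia has a mean of 2.82 CPM in controls and 273 CPM at 6 h.

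At 2 d, the comparison with control asks which changes follow the first hours. Astrocytes held most of the calls in the planned fit, though not with the library set as a term. Vim, the filament protein of reactive astrocytes, rose by 4.01 ± 0.66 from 35.0 CPM ± 11.4 to 560 CPM ± 201 (edgeR adjusted p = 0.00718), Gfap by 2.45 ± 0.61 to 657 CPM ± 61.3 (edgeR adjusted p = 0.0269) and the protease inhibitor gene Serpina3n by 3.91 ± 0.82 (edgeR adjusted p = 0.0154). Timp1, an inhibitor of matrix metalloproteases, had 2 UMIs in control astrocytes and 395 at 2 d, a ratio of 122 (95% counting interval 33.5 to 1010), and Lcn2 had none in controls and 156 at 2 d, at least 32.1-fold higher. The reactive astrocyte list rose with a median of 2.76, with 14 of 17 members up adjusted over the list alone and 9 over all genes tested (camera adjusted p = 4.68e-12, adjusted p = 0.38 with an estimated correlation). Genes of astrocyte homeostasis rose as well: the folate enzyme gene Aldh1l1 by 1.82 ± 0.28 (edgeR adjusted p = 0.00718), the potassium channel gene Kcnj10 by 1.76 ± 0.34 and the water channel gene Aqp4 by 1.40 ± 0.34. In that list 4 of 16 rose both adjusted over the list alone and over all genes tested (camera adjusted p = 1.08e-05, adjusted p = 0.449 with an estimated correlation).

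Complement and antigen presentation genes rose in astrocytes at 2 d, 7 of 8 adjusted over the list alone and 5 over all genes tested (camera adjusted p = 6.83e-07, adjusted p = 0.33 with an estimated correlation). These included the complement genes C1qb (2.15 ± 0.46) and C1qc (2.14 ± 0.48), which are typical of microglia, and the major histocompatibility gene H2-D1 (1.75 ± 0.47). Along with them, 20 of 24 measured microglia-enriched genes, those at least 10 times higher in control microglia than in any other class, were higher in astrocytes (median 0.96), and Csf1r, a receptor of microglia, was at 17.3 CPM ± 2.47 against 9.46 CPM ± 3.06. Interferon response genes rose with 6 of 8 up adjusted over the list alone and 5 over all genes tested (camera adjusted p = 5.58e-05, adjusted p = 0.337 with an estimated correlation), among them Bst2 (3.11 ± 0.88), Ifit3 (2.69 ± 0.77) and Ifit3b (2.64 ± 0.77). Reads of Ifit3 and Ifit3b, and those of H2-D1, Serpina3n and C4b, can be shared with close copies, so these values are uncertain.

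Synapse and neurotransmission genes fell in astrocytes at 2 d, 15 of 22 adjusted over the list alone and 11 over all genes tested, with a median of -0.81 (camera adjusted p = 2.55e-08, adjusted p = 0.337 with an estimated correlation). Camk2a, a kinase of excitatory synapses, fell by 1.67 ± 0.26 from 371 CPM ± 112 to 117 CPM ± 7.75, and the glutamate receptor genes Grin2b by 1.71 ± 0.31 and Grin2a by 1.61 ± 0.30. Meg3, a long noncoding RNA abundant in neurons, fell by 2.34 ± 0.47 and Lars2, which holds a sequence like mitochondrial ribosomal RNA and is uncertain for that, by 2.77 ± 0.77. For both, control 3 lay far below controls 1 and 2, at 2374 CPM against 7744 and 9610 CPM for Meg3 and 493 CPM against 2395 and 2210 CPM for Lars2. With the library set as a term the log2 fold changes were -0.87 and -0.98, and for Grin2b, Camk2a and Grin2a -0.96, -1.07 and -0.89. These are genes of neurons, and Camk2a UMIs were found in 22.27% of astrocyte nuclei (median 1240 UMIs) against 77.76% of excitatory neurons (median 2458 UMIs). Slc17a7, the vesicular glutamate transporter that astrocytes should lack, was found in 37.35% of astrocyte nuclei against 86.49% of excitatory neurons. Its level in astrocytes was 495 CPM ± 111 in controls, 662 CPM ± 88.1 at 6 h, 324 CPM ± 25.9 at 2 d and 324 CPM ± 44.5 at 4 d. Nrgn, found in 79.2% of astrocyte nuclei, did not follow, at 1430 CPM ± 184 at 2 d and 1550 CPM ± 495 at 4 d against 1190 CPM ± 336.

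Microglia and macrophages at 2 d raised Cd74, the chaperone of class II antigen presentation, by 4.62 ± 0.83 from 5.59 CPM ± 5.47 to 151 CPM ± 92.6 (edgeR adjusted p = 0.0401), and the lysosomal reductase gene Ifi30 by 3.79 ± 0.47 (edgeR adjusted p = 0.0066). Cenpf, a centromere protein of dividing cells, had 2 UMIs in controls and 202 at 2 d, a ratio of 58.7 (95% counting interval 16 to 488). The neuronal chloride transporter gene Slc12a5 fell by 1.56 ± 0.24 and Kitl, the KIT ligand gene, by 1.45 ± 0.23. Most other neuronal RNA was lower in microglia as well, with Snap25 at 1050 CPM ± 201 against 1710 CPM ± 348 and Camk2a at 324 CPM ± 13.6 against 474 CPM ± 47.9. Nrgn was not, at 2250 CPM ± 413 against 1890 CPM ± 1190. Of 1655 genes higher in neurons, by the measure used for astrocytes, 1206 were lower. Adjusted over the list alone, 12 of 14 complement and antigen presentation genes rose (1 over all genes tested; camera adjusted p = 2.24e-13, adjusted p = 0.33 with an estimated correlation), as did 5 of 6 proliferation genes (1 over all genes tested; camera adjusted p = 9.65e-08, adjusted p = 0.33 with an estimated correlation). The interferon response list moved up with 11 of 13 members up adjusted over the list alone (camera adjusted p = 1.43e-08, adjusted p = 0.337 with an estimated correlation), and the disease-associated microglia list with 6 of 15 (camera adjusted p = 2.89e-07, adjusted p = 0.415 with an estimated correlation). P2ry12 was at 433 CPM ± 132 against 421 CPM ± 84.3 in controls (edgeR adjusted p = 0.961). Mki67, a marker of dividing cells, was at 92.5 CPM ± 65.3 against 2.39 CPM ± 2.67 (edgeR adjusted p = 0.0608).

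In vascular cells at 2 d, the cathepsin gene Ctss rose by 2.29 ± 0.36 and C1qc by 2.11 ± 0.36, and the synaptic gene Unc13a fell by 1.60 ± 0.27. Ctss and C1qc are typical of microglia, and 25 of 26 measured microglia-enriched genes were higher along with them (median 1.13). Csf1r was at 42.4 CPM ± 7.04 against 21.1 CPM ± 15.4. Of 1668 genes higher in neurons, by the same measure, 1237 were lower. Up adjusted over the list alone were 9 of 17 extracellular matrix genes (1 was down; camera adjusted p = 5.77e-06, adjusted p = 0.393 with an estimated correlation), 6 of 11 complement and antigen presentation genes (camera adjusted p = 2.32e-08, adjusted p = 0.33 with an estimated correlation) and 2 of 16 genes of the blood-brain barrier (camera adjusted p = 0.00449, adjusted p = 0.593 with an estimated correlation). Col4a1, a collagen of the vessel wall, was at 129 CPM ± 42.2 in controls, 355 CPM ± 63.1 at 6 h and 250 CPM ± 58.1 at 2 d, with edgeR adjusted p of 0.0586 and 0.196.

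In oligodendrocytes at 2 d, Ccdc24, a coiled-coil protein gene, rose by 1.73 ± 0.25 (edgeR adjusted p = 0.0473). Lists of complement and antigen presentation (6 of 7 up adjusted over the list alone; camera adjusted p = 2.73e-06, adjusted p = 0.337 with an estimated correlation), myelin (2 of 14; camera adjusted p = 0.00195, adjusted p = 0.536 with an estimated correlation) and reactive oligodendrocytes (6 of 14, with 2 down; camera adjusted p = 0.0426, adjusted p = 0.61 with an estimated correlation) moved up. Microglia-enriched genes were higher too, 15 of 19 measured (median 0.80). Serpina3n was at 84.3 CPM ± 53.8 against 3.75 CPM ± 1.17 (edgeR adjusted p = 0.132) and C4b, a complement gene, at 113 CPM ± 74.3 against 11.2 CPM ± 7.97 (edgeR adjusted p = 0.173). In precursors, proliferation genes moved up with a median of 1.90 and 11 of 14 members up adjusted over the list alone (camera adjusted p = 1.12e-12, adjusted p = 0.33 with an estimated correlation). Their Mki67 was at 72.1 CPM ± 26.4 against 10.4 CPM ± 4.10 (edgeR adjusted p = 0.111) and Top2a, a topoisomerase of dividing cells, at 104 CPM ± 36.3 against 17.3 CPM ± 10.6 (edgeR adjusted p = 0.15).

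In neurons at 2 d, interferon response genes moved up in excitatory neurons with a median of 1.01 (camera adjusted p = 1.72e-06, adjusted p = 0.33 with an estimated correlation) and in inhibitory neurons with 0.56 (camera adjusted p = 0.0331, adjusted p = 0.399 with an estimated correlation). Complement and antigen presentation genes moved up with medians of 1.03 and 1.32. Their camera adjusted p was 8.58e-05 and 0.000202, and 0.38 and 0.382 with an estimated correlation. Of microglia-enriched genes, 34 of 57 measured were higher in excitatory neurons (median 0.16) and 15 of 20 in inhibitory neurons (median 0.41). The synapse and neurotransmission list of excitatory neurons had a median of -0.10 (camera adjusted p = 0.373). In excitatory and inhibitory neurons edgeR called 0 single genes, with 1379 and 1533 at an unadjusted p under 0.05, and DESeq2 called 52 and 64.

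At 2 d, edgeR called 988 genes in astrocytes (355 up, 633 down), 24 in microglia (20 up, 4 down), 8 in vascular cells (7 up, 1 down) and 1 in oligodendrocytes (up), and 0 in precursors (1559 at an unadjusted p under 0.05, 51 by DESeq2). Of the 1021 calls over the classes, 2 were among the 76 called with the library set as a term. Of these 76, 2 were up and 74 down, against 383 up and 638 down without the term, and those in astrocytes (6), microglia (8) and vascular cells (7) were all down. Among the 28 named calls, 1 was called with that term (Slc12a5), and all 28 kept their sign. With that term the log2 fold changes of further calls were 0.71 for H2-D1, 1.73 for Bst2 and 1.83 for Ifit3b, 3.66 for Cd74, 8.86 for Cenpf and 9.87 for Timp1. The total moved to 193 without control 1, 61 without control 2, 15677 without control 3, 224 without 2 d library 1, 171 without 2 d library 2 and 104 without 2 d library 3. Aldh1l1, Camk2a and Vim in astrocytes were called in every fit that left out 1 library. The highest adjusted p of the others was between 0.0509 and 0.262. Of the 28 calls, 18 ended without control 1, 22 without control 2, 13 without 2 d library 1, 15 without 2 d library 2 and 20 without 2 d library 3. Without the other libraries between 0 and 8 ended. The list calls of the blood-brain barrier (0.0964) and of interferon response in inhibitory neurons (0.0868) ended without control 3. The latter also ended without control 2 (0.0952) or 2 d library 3 (0.174). That of reactive oligodendrocytes ended without control 3 (0.414), 6 h library 1 (0.06) or 2 d library 3 (0.11).

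At 4 d, the comparison with control asks which changes were present at the last time studied. In astrocytes, Vim rose by 3.13 ± 0.64 to 303 CPM ± 214 (edgeR adjusted p = 0.0375), Myoc by 2.09 ± 0.36 to 364 CPM ± 141 (edgeR adjusted p = 0.0318), Aldh1l1 by 1.35 ± 0.28 and C1qb by 2.05 ± 0.46. The ion exchanger gene Slc24a5 fell by 2.47 ± 0.36 (edgeR adjusted p = 0.0318), the lupus brain antigen gene Trank1 by 2.11 ± 0.40, Grin2b by 1.58 ± 0.30, Camk2a by 1.52 ± 0.26 and Grin2a by 1.26 ± 0.29. Trank1 was at 68.3 CPM in control 3 against 300 and 216 CPM in controls 1 and 2, and with the library set as a term its log2 fold change was -0.59. Slc24a5 was highest in control 3, at 148.6 CPM against 58.95 and 81.63 CPM in controls 1 and 2. It was also a leading gene of excitatory-neuron cluster 4. That cluster held 46.25% of the kept nuclei of control 3 and at most 1.98% of those of any other library. Whether the fall of Slc24a5 arose in astrocytes themselves was not tested. Gfap was at 380 CPM ± 248 (edgeR adjusted p = 0.135) and Serpina3n at 66.9 CPM ± 48.3 against 8.50 CPM ± 4.83 (edgeR adjusted p = 0.0756). For these and for Vim, 4 d library 2 stood apart, near the controls. Gfap was at 94.7 CPM there against 502 and 544 CPM in libraries 1 and 3. Serpina3n was at 11.1 CPM against 96.7 and 92.9 CPM, and Vim at 59.2 CPM against 460 and 389 CPM. In the same library Myoc (202 CPM), Aldh1l1 (140 CPM) and C1qb (65.5 CPM) were above each control, and Camk2a (144 CPM) was below each. Up adjusted over the list alone were 2 of 17 reactive astrocyte genes (camera adjusted p = 4.61e-05, adjusted p = 0.519 with an estimated correlation), 9 of 16 of astrocyte homeostasis (camera adjusted p = 2.82e-07, adjusted p = 0.415 with an estimated correlation), 8 of 8 of complement and antigen presentation (camera adjusted p = 1.33e-07, adjusted p = 0.33 with an estimated correlation) and 4 of 8 of the interferon response (camera adjusted p = 0.00224, adjusted p = 0.412 with an estimated correlation). Of the synapse list, 13 of 22 fell adjusted over the list alone and 3 over all genes tested (camera adjusted p = 9.85e-08, adjusted p = 0.38 with an estimated correlation).

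In microglia at 4 d, edgeR called 0 genes over all genes tested, with 1115 at an unadjusted p under 0.05 and 16 called by DESeq2. Complement and antigen presentation genes moved up, 13 of 14 adjusted over the list alone (camera adjusted p = 3.7e-14, adjusted p = 0.33 with an estimated correlation), as did disease-associated microglia genes, 7 of 15 (camera adjusted p = 6.77e-11, adjusted p = 0.337 with an estimated correlation), and interferon response genes, 4 of 13 (camera adjusted p = 2.25e-07, adjusted p = 0.38 with an estimated correlation). The proliferation list had a median of 1.17 (camera adjusted p = 0.0101, adjusted p = 0.449 with an estimated correlation). Cd74 was at 123 CPM ± 71.8 (edgeR adjusted p = 0.287) and Spp1, the osteopontin gene, at 482 CPM ± 434 against 2.14 CPM ± 1.94 (edgeR adjusted p = 0.401). Spp1 was at 600 and 845 CPM in 4 d libraries 1 and 3. In library 2 it was at 2.00 CPM, the level of the controls. Ccl4 was at 32.1 CPM ± 10.4 at 2 d and 10.4 CPM ± 8.64 at 4 d, with edgeR adjusted p of 0.0975 and 0.577. P2ry12 was at 418 CPM ± 130 (edgeR adjusted p = 0.992).

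In vascular cells at 4 d, lists of complement and antigen presentation, the blood-brain barrier and extracellular matrix moved up with medians of 1.13, 0.46 and 0.66. Their camera adjusted p was 9.85e-08, 0.000536 and 0.00175, and 0.33, 0.525 and 0.511 with an estimated correlation. Adjusted over the list alone, 4, 2 and 3 members rose. Col4a1 was at 171 CPM ± 79.0 and Lcn2 at 9.72 CPM ± 11.5 against 3.59 CPM ± 3.11 (edgeR adjusted p = 0.623 and 0.743). In oligodendrocytes, complement and antigen presentation, reactive oligodendrocyte and myelin lists moved up with medians of 1.62, 0.52 and 0.45. Their camera adjusted p was 9.85e-08, 0.0177 and 0.00582, and 0.33, 0.56 and 0.58 with an estimated correlation. Adjusted over the list alone by edgeR, 5, 5 and 0 members rose, and 1 of the reactive oligodendrocyte list fell. In precursors the proliferation list had a median of 0.64 (camera adjusted p = 0.00584, adjusted p = 0.5 with an estimated correlation), and Mki67 was at 31.8 CPM ± 29.3 (edgeR adjusted p = 0.545). Complement and antigen presentation genes moved up in excitatory and inhibitory neurons with medians of 1.11 and 1.25. Their camera adjusted p was 1.36e-06 and 0.000218, and 0.33 and 0.382 with an estimated correlation. The interferon list moved up in excitatory neurons (median 0.56, camera adjusted p = 0.002, adjusted p = 0.393 with an estimated correlation), and in inhibitory neurons its camera adjusted p was 0.255. At 4 d microglia-enriched genes were higher as well: 26 of 26 measured in vascular cells, 22 of 24 in astrocytes, 16 of 19 in oligodendrocytes, 40 of 57 in excitatory neurons and 16 of 20 in inhibitory neurons. The synapse list of excitatory neurons had a median of -0.17 (camera adjusted p = 0.23).

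At 4 d, edgeR called 143 genes in astrocytes (38 up, 105 down), 2 in inhibitory neurons (both down) and 0 in the other 5 classes. At an unadjusted p under 0.05 these 5 had 759 genes in excitatory neurons, 1057 in oligodendrocytes, 964 in precursors, 1115 in microglia and 1412 in vascular cells, and DESeq2 called 7, 9, 2, 16 and 45. Of the 145 calls, 3 were among the 98 called with the library set as a term. All 98 were down, against 38 up and 107 down without the term. Among the 9 named calls, 1 was called with that term (Slc24a5), and all 9 kept their sign. With that term Slc24a5 had a log2 fold change of -3.10, Grin2b of -0.82, Camk2a of -0.92 and Grin2a of -0.55. The total moved to 1 without control 1, 1 without control 2 and 11181 without control 3, to 95 without 6 h library 1 and 2 without 6 h library 3, and to 44 without 2 d library 1. It was 12 without 4 d library 2 and 0 without 2 d library 2, 2 d library 3, 4 d library 1 or 4 d library 3. None of the 9 named calls held in every such fit, with highest adjusted p between 0.186 and 0.282. Of the 9, 8 ended without control 1, 7 without 4 d library 2 and all 9 without control 2, 6 h library 3, 2 d library 2 or 3, or 4 d library 1 or 3. A further 3 ended without 6 h library 1 or 2 d library 1, and 1 without 6 h library 2. List calls that ended without control 3 were proliferation in microglia (0.0807) and precursors (0.0672), reactive astrocyte in astrocytes (0.098), extracellular matrix (0.0617), reactive oligodendrocyte (0.331) and interferon response in excitatory neurons (0.15). Interferon response there also ended without control 1 (0.107), proliferation in precursors without 4 d library 3 (0.539), and reactive oligodendrocyte without 4 d library 1 (0.102) or 3 (0.0973).

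**Figure D3:**
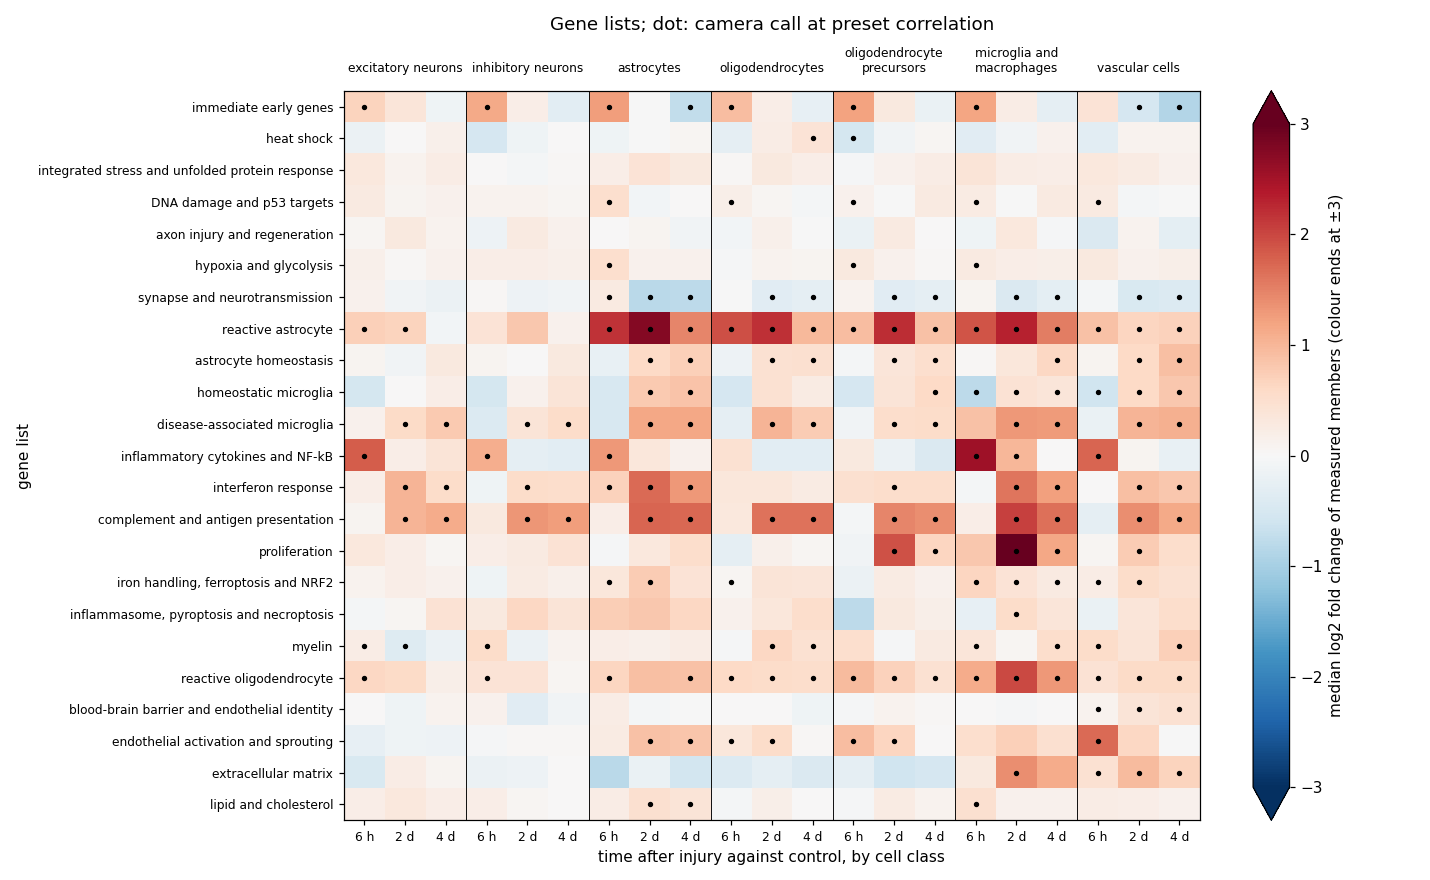
Median log2 fold change of gene lists against control by class and time. Marked cells passed camera at an adjusted p of 0.05 with the preset correlation; the reactive astrocyte list in astrocytes has medians of 2.16 at 6 h, 2.76 at 2 d and 1.47 at 4 d.

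Over 7 classes and 3 times, 166 of 483 list tests passed with camera, 149 up and 17 down: 51 at 6 h, 60 at 2 d and 55 at 4 d. With an estimated correlation 0 passed camera (smallest adjusted p = 0.33), and fry called 1. With the library set as a term 131 passed, 108 of them among the 166. Each list was tested 21 times. Reactive astrocyte passed in 17 tests, reactive oligodendrocyte in 16, disease-associated microglia and complement with antigen presentation in 14 each, and interferon response in 11, all up. Synapse and neurotransmission passed in 11, 10 of them down. Immediate early genes passed in 9 (6 up, 3 down), astrocyte homeostasis in 9 (up), homeostatic microglia in 9 (7 up, 2 down) and myelin in 9 (8 up, 1 down). Iron handling with ferroptosis and NRF2 passed in 8, endothelial activation in 7, cytokines and NF-kB in 6, DNA damage and p53 targets in 5, proliferation in 5 and extracellular matrix in 4, all up. Hypoxia and glycolysis, the blood-brain barrier list, and lipid and cholesterol passed in 3 each (up), heat shock in 2 (1 up, 1 down), and the inflammasome, pyroptosis and necroptosis list in 1 (up). The integrated stress and unfolded protein response list (smallest camera adjusted p = 0.0505) and the axon injury and regeneration list (0.081) passed in none.

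Genes that differed among the 3 injury times numbered 3110 in astrocytes, 1395 in microglia, 1305 in inhibitory neurons, 1235 in oligodendrocytes, 981 in excitatory neurons, 825 in vascular cells and 681 in precursors (edgeR F-test at an adjusted p of 0.05). The 6 h libraries belong to set A and all 2 d and 4 d libraries to set B, so these counts compare the sets as well as the times. Over the classes 9532 genes were called, and 38 with the set as a term, 15 of them among the 9532. The total moved to 20878 without control 3 and 14444 without control 1. It fell to 2010 without 6 h library 3, and lay between 4348 and 5378 without 6 h library 1 or 2, any 2 d library, or 4 d library 1 or 2. Between 4 d and 2 d, both in set B, edgeR called 0 genes over all classes, with 1535 at an unadjusted p under 0.05 and 7 called by DESeq2. That count was 1 without control 2 or 4 d library 2, 5 without control 3 and 11 without 2 d library 2.

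The genes called in every fit that left out 1 library lie as follows on GRCm38 (mm10), from the start to the end of the annotated protein-coding gene. Ccl3 (ENSMUSG00000000982) spans positions 83647844 to 83649355 of chromosome 11 and Ccl4 (ENSMUSG00000018930) 83662584 to 83664683 of the same chromosome. Slc7a11 (ENSMUSG00000027737) spans 49892526 to 50443614 of chromosome 3, Adamts9 (ENSMUSG00000030022) 92772699 to 92943492 and Aldh1l1 (ENSMUSG00000030088) 90486427 to 90600203 of chromosome 6. Vim (ENSMUSG00000026728) spans 13573927 to 13582826 of chromosome 2 and Camk2a (ENSMUSG00000024617) 60925618 to 60988152 of chromosome 18. UMIs were counted per gene and do not tell exons from introns here.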

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

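The tests in this part were chosen after the result was seen, except the F-test of the times and the prediction for the correlation between library sets in the next paragraph. The sets themselves were found by clustering after the data were seen. The test of neuronal genes was first run on called genes alone, at 4 times and then 1.5 times higher in neurons, and then on all genes, since the called ones were chosen for the pattern.

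Genes differing among 6 h, 2 d and 4 d were found in every class by edgeR's F-test of the times, 681 to 3110 per class. This is a difference between groups. Over the genes called, the log2 ratio of control 3 to controls 1 and 2 correlated with that of 2 d to 6 h in each class, with a smallest correlation of 0.67 and slopes of 0.34 to 0.51. Over all genes the correlations were 0.46 to 0.62. Control 3 had been placed in set B since its expression lay nearer to the 2 d and 4 d libraries. A positive correlation was thus built into the sets and is no test of them. The controls do differ without injury, so a difference between the sets that is not injury time may make up part of these differences. With the set as a term 38 genes were called over the classes, and since the term also widens the standard errors (median ratio 1.28 at 2 d) and rests on the controls, time after injury cannot be told apart from the sets.

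Of the 280 ways to divide the 9 injured libraries into 3 groups of 3, 50 were run, the real one included. As many genes were called in 3 of the 50 for excitatory neurons (real 981, highest other 1052) and 3 for inhibitory neurons (1305, 1463), so by these draws chance cannot be excluded there. It was 1 of the 50 for astrocytes (3110, 3009), oligodendrocytes (1235, 1129), precursors (681, 580), microglia (1395, 1333) and vascular cells (825, 812), a share under 0.05. The 2 other divisions that kept the 6 h libraries together called between 534 and 3009 genes per class, and the 47 that parted them at most 3. In all, 10 of the 280 keep the 6 h libraries together, and the rest of these were run after the draws were seen. Of the 10, as many genes were called in 10 for excitatory neurons (up to 1602), 10 for inhibitory neurons (2122), 2 for astrocytes (3147), 4 for oligodendrocytes (1346), 3 for precursors (757), 3 for microglia (1465) and 6 for vascular cells (1089). The difference between classes in the draws thus rests in part on which divisions were drawn. Keeping the 6 h libraries together keeps both the time and the injured libraries of set A together, so these divisions do not tell time from set.

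A cluster like hippocampal neurons, outside the 7 classes, was above its level in the controls at 2 d and 4 d, most of it in 1 library each. Cluster 14 made up 0.0424% ± 0.0302 of kept nuclei in controls, 0% at 6 h, 5.85% ± 8.33 at 2 d (0.285 to 15.4) and 3.46% ± 4.18 at 4 d (0.695 to 8.27). No explanation was tested for it.

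Neuronal genes were lower in astrocytes after injury: 385 of the 633 genes that fell at 2 d (60.8%) were at least 1.5 times higher in control excitatory neurons, against 11 of the 355 that rose (3.1%) and 14.6% of those tested. Less free neuronal RNA would lower such genes in every glial class. The median over all 1765 was -0.61 in astrocytes, and in 4 other classes the highest was -0.22, between the bounds set, which leaves free RNA open. Over the called genes alone the highest was -0.51, past the bound for free RNA, but these genes were chosen for the pattern. In astrocytes control 3 lay below controls 1 and 2 by a median of -0.48, consistent with a difference between the library sets, and with the set as a term the median at 2 d was -0.23, so time after injury cannot be told apart from it there. In microglia, vascular cells and oligodendrocytes control 3 differed by 0, -0.03 and -0.03, and the medians at 2 d were -0.30, -0.29 and -0.23 and with the set as a term -0.26, -0.24 and -0.18, which goes against the sets there but rests on control 3 alone, while precursors went with astrocytes (control 3 -0.15, median at 2 d -0.22 and with the set as a term -0.08).

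Microglial genes were higher in classes other than microglia. Of 62 genes at least 10 times higher in control microglia than in any other class, 17 to 57 were measured in each of the 6 other classes, and the lowest median at 4 d was 0.45 (inhibitory neurons, 20 genes), as microglial RNA in their droplets would give. With the set as a term the medians were 0.44 in excitatory and 0.30 in inhibitory neurons, 0.63 in astrocytes, 0.49 in oligodendrocytes, 0.77 in vascular cells and 0.26 in precursors, the last below the bound of 0.3. Expression of complement genes by these classes themselves would raise the 3 C1q genes beyond the rest: the median of their excess in the 6 classes was -0.05 relative to microglia. The excess was 1.02 in excitatory neurons and 1.09 in oligodendrocytes, above the 0.86 of microglia, and 0.83, 0.79, 0.68 and 0.76 in inhibitory neurons, astrocytes, precursors and vascular cells, which leaves it open.

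For each comparison with control the 6 libraries divide in 10 ways, too few for a share under 0.05. Divisions with as many genes at 6 h, with the real and the highest other count, were 2 for excitatory neurons (1, 6), 1 for inhibitory neurons (12, 1), 1 for astrocytes (34, 5), 2 for oligodendrocytes (4, 18), 10 for precursors (0, 8), 1 for microglia (145, 3) and 1 for vascular cells (69, 12). At 2 d they were 10 (0, 0), 10 (0, 2), 1 (988, 0), 1 (1, 0), 10 (0, 1), 1 (24, 0) and 1 (8, 0) in the same order. At 4 d they were 10 (0, 2639), 2 (2, 2940), 2 (143, 375), 10 (0, 835), 10 (0, 886), 10 (0, 167) and 10 (0, 426), each highest where controls 1 and 2 were joined with 4 d library 3 against control 3 with the other 4 d libraries. That division points to a structure of the samples, and with the library set as a term the counts at 4 d were 27, 25, 7, 13, 12, 4 and 10. Between 4 d and 2 d each class had 10 of 10 (0, 0), with 1 as the highest other in microglia. Lists called gave 2 at 6 h (50, 65), 1 at 2 d (61, 46) and 3 at 4 d (55, 65), adjusted within each comparison. The other divisions called a median of 24 lists at 6 h, 25 at 2 d and 22 at 4 d. Of these divisions 7, 9 and 9 called at least 1 list.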

How the results depend on the processing

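The alternatives listed above as added later, with the comparison of 4 d with 2 d, were chosen after the result was seen. So were the genes and lists followed here, a choice shortened after alternatives had been computed. The cause was not tested for any change below. Counts of genes are in the order excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, precursors, microglia and vascular cells, and shares are log2 fold changes unless stated. Results not given under an alternative kept their direction and side of the threshold there, or stayed within 1.5 times the count, apart from the named genes and lists counted at the end. Replicate numbers did not pair the libraries: over 18 pairs of the same number the correlation of log expression less its group mean ran from -0.61 to 0.22 with a median of -0.05.

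With DESeq2's size factors in place of TMM, the genes called were 6 in excitatory neurons at 6 h, and 0 in oligodendrocytes at 2 d. With no filter on low counts, the genes called were 61, 521, 1022, 1046, 700, 912, 816 at 6 h, then 2, 27, 1784, 465, 330, 735, 440 at 2 d, then 3, 2, 1067, 140, 80, 181, 295 at 4 d, then 1161, 1720, 4023, 2541, 1784, 2389, 2039 among the injury times, then 161 between 4 d and 2 d. At 4 d P2ry12 in microglia changed direction (0.03). With DESeq2, the genes called were 445, 950, 374, 241, 145, 356, 199 at 6 h, then 52, 64, 1250, 113, 51, 247, 128 at 2 d, then 7, 8, 569, 9, 2, 16, 45 at 4 d, then 2393, 2300, 3401, 1776, 1090, 1763, 1373 among the injury times, then 7 between 4 d and 2 d. With only the groups compared in the fit, the genes called were 0, 0, 0, 1, 0, 8, 17 at 6 h, then 0, 0, 190, 0, 0, 1, 0 at 2 d, then 0 in inhibitory neurons and 0 in astrocytes at 4 d, then 3455, 3412, 4220, 2699, 2001, 2406, 2127 among the injury times, then 6 between 4 d and 2 d. At 4 d P2ry12 in microglia changed direction (0.01).

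With the replicate number as a block, the genes called were 2, 0, 15, 2, 1, 84, 19 at 6 h, then 0, 0, 569, 1, 8, 54, 0 at 2 d, then 0, 1, 0, 1, 1, 3, 0 at 4 d, then 112, 43, 2510, 625, 25, 980, 269 among the injury times, then 4 between 4 d and 2 d. Of shares, inhibitory neurons at 2 d (-0.54), astrocytes at 2 d (0.91), astrocytes at 4 d (0.95) and microglia at 4 d (1.17) no longer passed. Without nuclei above the 95th percentile of UMIs, the genes called were 21 in astrocytes at 6 h, then 0, 1, 724, 3, 3, 84, 52 at 2 d, then 0 in inhibitory neurons and 25 in astrocytes at 4 d. At 4 d P2ry12 in microglia changed direction (0.08). With only nuclei whose highest marker score was that of their class, the genes called were 1 in inhibitory neurons and 1 in vascular cells at 2 d, and 83 in astrocytes at 4 d. Of shares, inhibitory neurons at 2 d (-0.54) and microglia at 4 d (1.19) no longer passed. At 4 d P2ry12 in microglia changed direction (0.01). With the same number of nuclei per library, the genes called were 0, 5, 18, 4, 0, 41, 33 at 6 h, then 0, 2, 859, 12, 16, 56, 0 at 2 d, then 0 in inhibitory neurons and 262 in astrocytes at 4 d, then 425 in excitatory neurons and 506 in vascular cells among the injury times. P2ry12 in microglia at 4 d (0.05), Mki67 in microglia at 6 h (-0.01), Mki67 in precursors at 6 h (1.16) and Top2a in precursors at 6 h (0.33) changed direction.

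With TMM factors over the classes, of shares, astrocytes at 6 h (-0.07), oligodendrocytes at 6 h (0.00), precursors at 6 h (-0.45), microglia at 6 h (-0.23), precursors at 2 d (-0.40), oligodendrocytes at 4 d (-0.25) and precursors at 4 d (-0.46) changed direction, and inhibitory neurons at 2 d (-1.14), astrocytes at 2 d (0.42), astrocytes at 4 d (0.28) and microglia at 4 d (0.52) no longer passed. With limma on arcsine square root shares, vascular cells passed at 4 d (a difference of 0.09 on that scale). With only nuclei of at least 1000 UMIs, of shares, microglia at 6 h (-0.01) and oligodendrocytes at 2 d (0.13) changed direction, astrocytes at 4 d (1.22) no longer passed, and microglia at 2 d (0.97) and vascular cells at 4 d (1.04) passed. Among non-neuronal nuclei, of shares, precursors at 6 h (-0.18), precursors at 2 d (-0.43), oligodendrocytes at 4 d (-0.43) and precursors at 4 d (-0.54) changed direction, and astrocytes at 2 d (0.37), astrocytes at 4 d (0.20) and microglia at 4 d (0.42) no longer passed.

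With the library set as a term, the genes called were 0 in excitatory neurons, 220 in inhibitory neurons and 20 in vascular cells at 6 h, then 21, 15, 6, 14, 5, 8, 7 at 2 d, then 27, 25, 7, 13, 12, 4, 10 at 4 d, then 6, 10, 5, 4, 0, 12, 1 among the injury times. Of shares, excitatory neurons at 2 d (-0.53), excitatory neurons at 4 d (-0.53) and oligodendrocytes at 4 d (-0.15) changed direction, and inhibitory neurons at 2 d (-0.40), astrocytes at 2 d (0.97), astrocytes at 4 d (1.02) and microglia at 4 d (1.33) no longer passed. P2ry12 in microglia at 4 d (0.16) and Top2a in precursors at 6 h (0.40) changed direction. The lists called at 4 d were 25, and the synapse list of excitatory neurons pointed up at 2 d (camera adjusted p = 0.83) and 4 d (0.867). With finer clusters, the genes called were 24 in excitatory neurons and 2 in inhibitory neurons at 6 h, then 0, 0, 1777, 0, 0, 39, 4 at 2 d, then 0 in inhibitory neurons and 1112 in astrocytes at 4 d, then 742 in inhibitory neurons among the injury times. Of shares, excitatory neurons at 4 d (-0.09) changed direction, astrocytes at 2 d (0.71) no longer passed, and excitatory neurons at 6 h (1.59), inhibitory neurons at 6 h (-0.98), inhibitory neurons at 4 d (-1.03) and vascular cells at 4 d (1.09) passed. The synapse list of excitatory neurons pointed up at 4 d (camera adjusted p = 0.935).

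With all deposited barcodes, the genes called were 2, 69, 20, 18, 0, 144, 89 at 6 h, then 0, 2, 1357, 2, 1, 10, 0 at 2 d, then 0 in inhibitory neurons and 414 in astrocytes at 4 d. P2ry12 in microglia at 2 d (-0.07) and Mki67 in precursors at 6 h (0.01) changed direction. With cluster 3 counted among excitatory neurons, they had 229 genes called at 6 h and 1 at 2 d. Without the 2 libraries with most unnamed nuclei, the genes called were 0, 0, 0, 1, 0, 15, 7 at 6 h, then 0, 0, 0, 0, 0, 0, 0 at 2 d, then 0 in inhibitory neurons and 0 in astrocytes at 4 d, then 9, 103, 2585, 443, 19, 777, 370 among the injury times. Of shares, excitatory neurons at 4 d (-0.11) and oligodendrocytes at 4 d (-0.05) changed direction, and inhibitory neurons at 2 d (-0.36) and microglia at 4 d (0.98) no longer passed. Mki67 in precursors at 6 h (0.25) changed direction.

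With an estimated correlation, camera called 0 lists at 6 h, 2 d and 4 d each, and fry called 1, 0 and 0. The median estimated correlation over the called lists was 0.29 against the preset 0.01.

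When 1 library was left out at a time, the lone pair of libraries in its group was taken to vary like the other groups. The shares ran as follows at 6 h: excitatory neurons 0.53 to 2.05, inhibitory neurons -0.36 to -0.17, astrocytes 0.34 to 0.63, oligodendrocytes 0.09 to 0.68, precursors 0.03 to 0.28, microglia 0.03 to 0.59 and vascular cells -0.51 to 0.11. At 2 d they ran: excitatory neurons -0.11 to 1.42, inhibitory neurons -0.62 to -0.43, astrocytes 0.78 to 1.08, oligodendrocytes -0.40 to 0.20, precursors 0.03 to 0.29, microglia 0.74 to 1.23 and vascular cells 0.54 to 1.07. At 4 d they ran: excitatory neurons -0.11 to 1.42, inhibitory neurons -0.40 to -0.22, astrocytes 0.80 to 1.12, oligodendrocytes -0.09 to 0.55, precursors 0.14 to 0.40, microglia 0.93 to 1.47 and vascular cells 1 to 1.19. Genes called ran from 0 to 1775, 0 to 1577, 0 to 495, 0 to 811, 0 to 513, 14 to 572, 3 to 627 at 6 h, from 0 to 1985, 0 to 2677, 59 to 3451, 0 to 2135, 0 to 1835, 2 to 1829, 0 to 1765 at 2 d, from 0 to 1301, 0 to 2110, 0 to 2783, 0 to 1467, 0 to 1289, 0 to 979, 0 to 1252 at 4 d, and from 12 to 3707, 9 to 3513, 1553 to 4321, 155 to 2761, 1 to 2000, 253 to 2470, 26 to 2106 among the injury times. Genes called between 4 d and 2 d ran from 0 to 11, and lists called from 38 to 70 at 6 h, 41 to 67 at 2 d and 34 to 74 at 4 d. Named genes that changed direction in such a fit had log2 fold changes of -0.03 to 1 (Vim in astrocytes at 6 h), -0.24 to 0.21 and -0.26 to 0.21 (P2ry12 in microglia at 2 d and 4 d), -0.36 to 1.69 (Mki67 in microglia at 6 h), -0.01 to 0.70 and -0.31 to 1.85 (Col4a1 and Lcn2 in vascular cells at 4 d), and -0.29 to 0.25 and -0.57 to 0.40 (Mki67 and Top2a in precursors at 6 h). None of these 8 had passed the test.

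Of the values of named genes under the other alternatives, 876 kept direction and side of the threshold, 223 no longer passed, 47 newly passed and 13 changed direction. In fits without 1 library these were 852, 305, 15 and 16. Of the values of described lists, 412 kept both, 134 no longer passed and 3 changed direction, and without 1 library 708 kept both and 24 no longer passed. With no filter on low counts, 264 of the 265 genes called at 6 h, 964 of the 1021 at 2 d and 144 of the 145 at 4 d were among those called. With DESeq2 these were 262, 995 and 142. Control 2 holds 126 excitatory neurons, or 6954 with cluster 3, which limits what can be said of that class.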

Other observations

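The values in this part come from planned list tests and from clusters, and were chosen after the results were seen. Some gene lists moved in classes where the report does not describe them. Hypoxia and glycolysis genes, which cells raise when oxygen is short, moved up at 6 h in precursors (median log2 fold change 0.30, camera adjusted p = 0.00617, adjusted p = 0.393 with an estimated correlation), microglia (0.26, camera adjusted p = 0.0202, adjusted p = 0.382 with an estimated correlation) and astrocytes (0.50, camera adjusted p = 0.04, adjusted p = 0.449 with an estimated correlation). Immediate early genes were down in vascular cells at 2 d (-0.50, camera adjusted p = 0.00485, adjusted p = 0.641 with an estimated correlation) and 4 d (-0.89, camera adjusted p = 1.24e-06, adjusted p = 0.449 with an estimated correlation).

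Interferon response genes moved up in vascular cells at 2 d (0.90, camera adjusted p = 8.46e-06, adjusted p = 0.393 with an estimated correlation), with 17 of 17 members higher, and at 4 d (0.82, camera adjusted p = 2.25e-07, adjusted p = 0.362 with an estimated correlation). In microglia the homeostatic list, down at 6 h, was up at 2 d (0.44, camera adjusted p = 0.00471, adjusted p = 0.617 with an estimated correlation) and 4 d (0.37, camera adjusted p = 0.00229, adjusted p = 0.598 with an estimated correlation). Microglia-enriched genes as a whole were higher there too, 56 of 62 at 2 d (median 0.70) and 52 of 62 at 4 d (median 0.43), and genes higher in neurons were lower, 1206 and 1127 of 1655, so the list did not exceed this general shift. Inflammasome, pyroptosis and necroptosis genes moved up in microglia at 2 d (0.56, camera adjusted p = 0.0117, adjusted p = 0.446 with an estimated correlation), with 9 of 9 members higher.

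Clusters outside the 7 classes differed widely between libraries. Striatal-neuron-like cluster 11 made up 3.02% ± 5.19 of kept nuclei in controls, 0.0212% ± 0.0184 at 6 h, 2.41% ± 3.24 at 2 d and 7.96% ± 6.74 at 4 d. Unnamed cluster 8 made up 1.35% ± 2.33 in controls, 13.2% ± 17.8 at 2 d and 4.16% ± 1.69 at 4 d. Unnamed cluster 20 made up 3.19% ± 3.09 in controls and 6.39% ± 5.59 at 6 h. Cluster 3 held 30.26% of the nuclei of control 1 and 63.56% of those of control 2.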
